A study of Bos taurus with 8 samples.

How the data were processed

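Rumen epithelium RNA from 4 Holstein bull calves was measured on 8 single-colour Agilent arrays, 1 per calf and diet. Per the labels, 500 ng of total RNA was labelled with Cy3 after linear amplification. Per the series text, 5 bulls were fed in a cross-over without a wash-out, 14 days on each diet, and the wood kraft pulp (WP) diet replaced 50% of the corn flakes of the high-grain control diet. Arrays of 4 of these animals, numbered 21, 23, 24 and 25, were analysed here. The diet order of each calf is not given in the sources used here.

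All 8 arrays lay on 1 slide of the bovine design 072598 and were scanned once, per the file headers. The deposited scanner files hold spot brightness as intensity, with a processed signal that the scanner software had already corrected for background, and per-spot flags; the software is Agilent Feature Extraction 11.0.1.1 per the file headers and 9.5 per the submitters' processing notes. The authors' deposited value table holds log2 values. Set against the scanner files, each of its columns was log2 of the processed signal minus 1 constant per array, with slopes between 0.99998 and 1.00 and medians from -3.07 to -2.26. Its scale and direction were thus settled by this comparison, its values were not centred by gene, and the table served as an alternative.

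For the comparison, log2 of the processed signal was scaled by subtracting each array's 75th percentile. The 536 control spots and 97 spots with an outlier flag were left out, and spots of 1 probe were averaged. Of 15008 probes, 10236 (68.2%) were well above background on at least 4 of 8 arrays and were tested. Depth has no count here: the number of arrays limits the precision. Between 9314 and 11990 probes per array were well above background. No spot was saturated.

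Probes were named through the RefSeq table of assembly ARS-UCD2.0, used for names only: 11194 by accession, 3085 by symbol and 38 by an older symbol, while 691 kept the name of the array design. Probe positions are those of the array design on UMD 3.1; the exon or UTR of a probe was not analysed here. A gene is represented by its brightest tested probe, which gave 10207 genes. A level is written relative to the array's own 75th percentile, and levels of different probes are not compared.

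The diets were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with calf as a block, since the labels give the same calf numbers on both diets and the series text states a cross-over. Deviations of a calf's 2 arrays from the diet means correlated weakly across probes, with r of 0.00840, 0.195, 0.0597 and 0.0471 for calves 21, 23, 24 and 25, so the pairing comes from the labels and not from the values. P-values were adjusted by Benjamini-Hochberg over all probes, with a threshold of 0.05. A sign-flip test of 1 gene over 4 calves cannot give an exact p under 0.125, so single genes have the limma test only. An error given as SD is that of the 4 within-calf differences, and SE is that of the fit.

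For gene groups, 31 lists with 722 members were fixed before the data were examined, 8 of them markers of other cell types that a biopsy of rumen wall can hold. The 29 lists with at least 5 tested genes were tested with camera (preset inter-gene correlation 0.01, adjusted over the lists), which compares a list with all other genes. The same test with an estimated correlation and limma's fry were run beside it. A list is written as called or shifted by the test with the preset correlation alone. Genes were named by a rule fixed before the data were examined: the 12 of smallest unadjusted p in each direction that went the same way in 4 of 4 calves, because none passed the threshold; the 4 members of smallest p of each list called; and 13 genes chosen in advance, of which MKI67 has no probe under that name. Uncharacterised LOC names were not named, and 2 genes that the rule takes are not reported here.

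The pipeline was tested on simulated data for this comparison, with 10194 probes, 200 of them changed, and 10 runs. It recovered 89.1% of 4-fold, 34.6% of 2-fold and 1.34% of 1.5-fold changes at the adjusted threshold. A simulated shift of -0.50 log2 in the cholesterol list was called in 10 of 10 runs. These simulated genes vary independently of each other.

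Alternatives covered the background correction (normexp with an offset of 50), quantile and cyclic loess scaling, the authors' value table, the filter on dim probes, the calf block, the slide row, the prior, the choice of probe, the thresholds and each calf left out. Cyclic loess scaling, the restriction to bright probes (median signal of at least 100) and the comparison within each slide row were chosen after seeing the data.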

Results

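Gene expression in rumen epithelium was compared between a high-grain diet and the same diet with wood kraft pulp (WP), a cellulose-rich fibre, in place of part of the corn. The question is how the epithelium's transcripts differ between the diets during a high-grain challenge. There were 4 arrays per diet, from the same 4 calves. Negative control spots had a median processed signal of 1.20 to 1.90 on 7 arrays and 4.06 on the WP array of calf 24. Probes against the viral E1A sequence, which serve as array controls, read 40.7 on that array and 1.36 to 1.97 on the others.

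**Figure D1:**
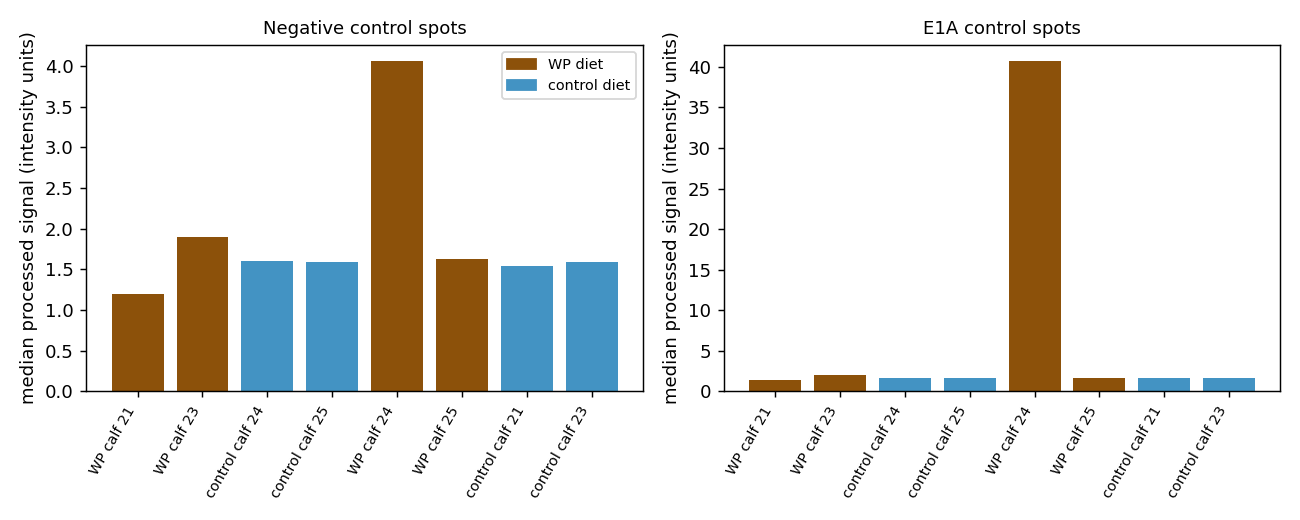
Median processed signal (intensity units, bars from 0) of negative control spots (left) and E1A control spots (right) on each of the 8 arrays, coloured by diet. The WP array of calf 24 stands at 4.06 and 40.7, above the other 7 arrays in both panels.

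The cytokine genes IL1A, IL36G and IL36A had lower values on the WP diet in every calf. IL1A, the cytokine interleukin 1 alpha (chromosome 11, 46349453 to 46349512), was lower by a log2 difference of -1.43 ± 0.45 (SD, n = 4 calves), a signal 2.70 times as high on the control diet. The interleukin 36 family cytokines IL36G (chromosome 11, 46549182 to 46549241) and IL36A (chromosome 11, 46572802 to 46572861) gave -1.70 ± 0.93 and -1.57 ± 0.85 (SD, n = 4). The receptor subunit IL22RA1 gave -1.19 ± 0.61 and AREG, the growth factor amphiregulin, -1.27 ± 0.62 (SD, n = 4). Other genes with lower values in 4 of 4 calves were ACER1, a ceramidase (-1.17), SPTSSB, a subunit of the enzyme that starts sphingolipid synthesis (-0.96), AHSG (-1.49), MFSD12 (-1.23), TMPRSS11BNL (-1.16), ABHD2 (-0.87) and BTBD17 (-0.57). None of these passed the threshold: each had an adjusted p of 0.658 in limma. The same direction in 4 of 4 calves is part of the rule that named them. Of all 10236 probes tested, 552 were lower and 1221 higher in 4 of 4 calves, together 17.3% against 12.5% by chance. Of the 12 genes named as lower, 8 lay below the median probe signal of 113, and their differences were smaller in size with normexp background correction, at -0.87 for IL1A, -0.88 for IL36G, -0.25 for AREG, -0.50 for AHSG, -0.071 for ACER1, which was above background on 2 of 4 WP arrays, and 0.050, with the sign turned, for BTBD17. AREG and BTBD17 were above background on 3 of 4 WP arrays.

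The 12 genes named for higher values in 4 of 4 calves were dim, and all lay below the same median signal. LMO3 gave 0.92 ± 0.19, MN1 1.19 ± 0.41, LRIG3 0.92 ± 0.26 and the fibroblast growth factor FGF2 0.90 ± 0.34 (SD, n = 4). CLK1, a splicing kinase, gave 0.60, ITIH4 0.82, ZNF362 0.89, CAMKMT 0.80, TMEM88B 0.77 and ASMT 0.66. BCL2L10 (0.87) and GNAQ (0.65) were higher with the main scaling and turned to -0.11 and -0.078 with quantile scaling. With normexp background correction LMO3 gave 0.38, MN1 0.39, LRIG3 0.45 and FGF2 0.40. MN1 was above background on 3 WP arrays and 1 control array, so the size of its difference is not set. BCL2L10 was above background on 2 and 3, and CAMKMT on 4 and 3. Each of the 12 had an adjusted p of 0.658.

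**Figure D2:**
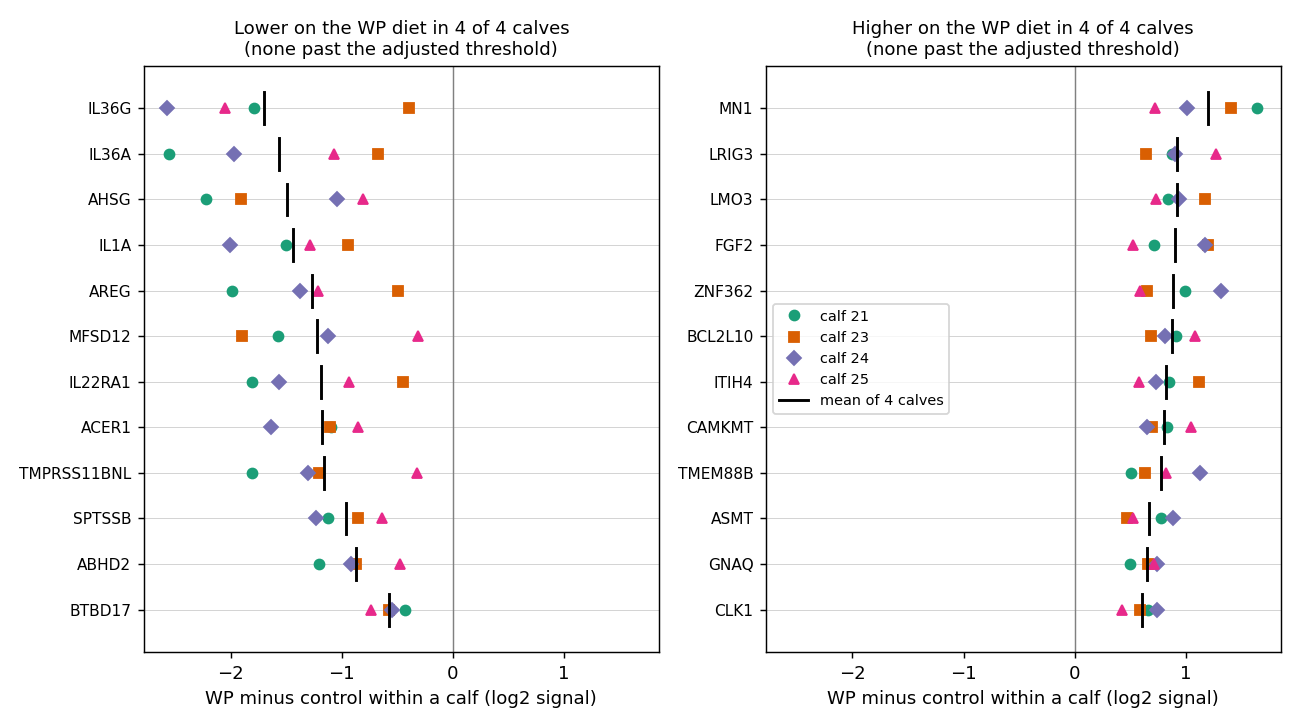
Within-calf difference in log2 signal, WP minus control (x axis), for the 12 genes named as lower (left) and the 12 named as higher (right); points are calves and the black bar is their mean. The means run from -1.70 for IL36G to -0.57 for BTBD17 on the left and from 0.60 for CLK1 to 1.19 for MN1 on the right.

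Across the array, 0 of 10236 probes passed an adjusted p of 0.05 in limma with calf as a block, and the smallest adjusted p was 0.658. At an unadjusted p under 0.05 there were 715 probes, against 512 by chance, of which 536 were higher and 179 lower on the WP diet. Quantile scaling, which moved the median difference of all probes from 0.09 to -0.02 log2, gave 192 higher and 336 lower, so that the share of lower probes went from 25.0% to 63.6%. Without calf 24, 264 were higher and 165 lower, and without calf 21, 411 were higher and 69 lower. With slide row as a second block there were 668 higher and 349 lower. Within slide row 1, which compares the WP arrays of calves 21 and 23 with the control arrays of calves 24 and 25, 393 were higher and 256 lower. Within row 2 there were 355 and 109, and neither row gave a probe past the adjusted threshold.

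Terminal differentiation genes of the stratified epithelium shifted lower as a group on the WP diet. Of 19 tested members of the cornified layer list, 17 had negative differences, 0 passed alone and 0 passed when adjusted over the list alone. Over the 18 members with a value on all 8 arrays, the median was -0.50 log2 (camera adjusted p = 5.95e-06; adjusted p = 0.599 with an estimated correlation). IVL, the cornified envelope precursor involucrin, gave -1.07 ± 0.99, and SPINK5, a protease inhibitor of the outer layers, -0.94 ± 0.68. CST6, a cysteine protease inhibitor, gave -0.76 ± 0.47 (SD, n = 4). KRT10, a suprabasal keratin, went the other way with 0.50 ± 0.48, though it was 0.29 without calf 21 and -0.38 within slide row 1. The list's median was negative in 3 of 4 calves, at -0.74, -0.37 and -0.68, and 0.27 in calf 25. Without calf 21 it was -0.25, without calf 24 -0.31, with normexp background correction -0.26 and within slide row 2 -0.21. The basal cell and basement membrane list had a positive median, 0.25, and was not called (camera adjusted p = 0.295). Its median was 0.76 in calf 21, 0.34 in calf 23, -0.10 in calf 24 and -0.20 in calf 25, and 0.077 without calf 21.

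In the cell cycle list 24 of 29 members had negative differences, with a median of -0.27 (camera adjusted p = 6.03e-07; adjusted p = 0.599 with an estimated correlation). The MCM helicase subunits led it: MCM3 gave -0.60 ± 0.33, MCM6 -0.34 ± 0.23 and MCM4 -0.27 ± 0.17 (SD, n = 4). None passed alone or when adjusted over the list alone. The list's median was -0.84 in calf 24, whose WP array had the raised control-spot signal, -0.29 in calf 25, 0.23 in calf 23 and -0.0050 in calf 21. Without calf 24 the call was lost (median -0.048, adjusted p = 0.0783). Over 16 alternatives the list's median ran from -0.42 to -0.048.

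Sterol and energy metabolism lists shifted lower as well by camera, though the cholesterol and mitochondrial medians were negative in 2 of 4 calves each. Of 24 cholesterol biosynthesis genes, 22 had negative differences, with a median of -0.26 (camera adjusted p = 7.67e-06; adjusted p = 0.599 with an estimated correlation). CYP51A1, an enzyme of sterol demethylation, gave -0.61 ± 0.47 and DHCR7 -0.49 ± 0.45 (SD, n = 4), while HMGCS1, an early enzyme of the pathway, gave -0.47 ± 0.84. Without calf 21, HMGCS1 gave -0.10 and DHCR7 -0.32. The list's median was -0.66 and -0.55 in calves 21 and 23 and 0.10 and 0.13 in calves 24 and 25. Without calf 21 the list's median was -0.025 and without calf 23 it was -0.14. In glycolysis and glucose uptake 16 of 21 members were negative, with a median of -0.16 (camera adjusted p = 1.28e-05; adjusted p = 0.599 with an estimated correlation), with PGK1 at -0.39 ± 0.24 and the hexokinase HK1 at -0.33 ± 0.17 (SD, n = 4). PFKFB4, well above background on 1 of 4 WP arrays, has no set direction, at -0.36 and, with normexp background correction, 0.13. The mitochondrial respiratory chain list had a median of -0.09 with 22 of 26 members negative (camera adjusted p = 0.000498; adjusted p = 0.729 with an estimated correlation), and its call was lost without calf 25 (median -0.0028, adjusted p = 0.159) and with quantile scaling (adjusted p = 0.120). The mitochondrial list's median was 0.044 and 0.069 in calves 21 and 23 and -0.088 and -0.34 in calves 24 and 25. The cholesterol and mitochondrial medians thus changed sign with the slide row of the WP array. Between rows (row 1 minus row 2) the medians were -0.34 for cholesterol and 0.14 for mitochondrial, larger in size than between the diets. In the cholesterol, glycolysis and mitochondrial lists 0 members passed when adjusted over the list alone.

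Inflammatory and antimicrobial lists shifted lower. In the cytokine and chemokine list 15 of 21 members were negative, with a median of -0.14 (camera adjusted p = 0.000148; adjusted p = 0.599 with an estimated correlation). IL1A alone passed when adjusted over the list alone (adjusted p = 0.0151). That adjustment was made separately in each of the 31 lists, without correction for their number. Over all probes IL1A had an adjusted p of 0.658 in limma. The neutrophil chemoattractant CXCL8 (chromosome 6, 90563357 to 90563416) was well above background on 4 control arrays and 1 WP array, so the size of its difference is not set. It was -2.69 ± 1.90 (SD, n = 4) with the main processing, -0.45 with normexp background correction and -1.77 without calf 21. IL1RN, the interleukin 1 receptor antagonist, gave -0.47 ± 0.20. IL1B, above background on 3 arrays of each diet, gave -0.10 ± 1.34 and was 0.43 without calf 21. The list's median was -0.74 in calf 21, -0.23 in calf 23, 0.0059 in calf 24 and -0.018 in calf 25. Without calf 21 it was 0.0090 and the call was lost (adjusted p = 0.104). In calf 21 the medians of macrophage and dendritic cell markers (-1.20) and of antigen presentation genes (-1.02) were negative as well. In the pattern recognition and antimicrobial list 13 of 20 members were negative, with a median of -0.16 (camera adjusted p = 0.000148; adjusted p = 0.599 with an estimated correlation). DUOXA2, needed for the hydrogen peroxide producing oxidase DUOX2, gave -1.89 ± 1.25, DUOX2 -0.52 ± 0.26 and LBP, the lipopolysaccharide binding protein, -1.10 ± 0.93 (SD, n = 4). TAP, the tracheal antimicrobial peptide, gave -3.32 ± 3.18, with -7.93 in calf 21 and -2.84, -1.66 and -0.84 in calves 24, 25 and 23, and -1.78 without calf 21. The median of the antimicrobial list was -0.58, -0.22, -0.031 and 0.033 in calves 21, 23, 24 and 25, and it was -0.10 without calf 21, -0.095 without calf 23 and 0.046 with no filter on dim probes. TLR4, the lipopolysaccharide receptor, gave 0.08 ± 0.70 and -0.34 with quantile scaling.

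The stress lists shifted lower by small medians. Oxidative stress and glutathione had 14 of 24 members negative, a median of -0.08 and a negative median in 4 of 4 calves (camera adjusted p = 0.00347; adjusted p = 0.599 with an estimated correlation). PRDX6, a peroxiredoxin, gave -0.53 ± 0.42 (SD, n = 4), though -0.34 without calf 21 and 0.22 within slide row 1, where the list was not called (adjusted p = 0.364). With the preset correlation the list was called in 12 of 16 alternatives, not with quantile scaling (adjusted p = 0.107), and its median was -0.020 without calf 25. Heat shock and unfolded protein response had a median of -0.13 with 16 of 26 members negative (camera adjusted p = 0.0211; adjusted p = 0.708 with an estimated correlation). Its member of smallest p, DDIT3, a transcription factor induced by endoplasmic reticulum stress, went the other way with 0.72 ± 0.56. The list's median was -0.55 and -0.13 in calves 21 and 23 and 0.19 and 0.21 in calves 24 and 25. With the preset correlation the list was called in 12 of 16 alternatives, not without calf 21 (median 0.049, adjusted p = 0.821) nor with quantile scaling (adjusted p = 0.493).

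Markers of 2 other cell types shifted higher and of 1 shifted lower beside these epithelial groups. Of 13 fibroblast and connective tissue genes, 12 had positive differences, with a median of 0.61 (camera adjusted p = 0.0209; adjusted p = 0.729 with an estimated correlation). POSTN, the matrix protein periostin, gave 0.75 ± 0.50 and PDGFRA, a fibroblast receptor above background on 3 WP and 2 control arrays, 0.90 ± 0.74 (SD, n = 4). The list's median was -0.87 in calf 21 and 0.63, 1.01 and 1.34 in the others, and it was 0.99 without calf 21 and 0.30 without calf 25. With the preset correlation the list was called in 11 of 16 alternatives, and the call was lost without calf 23 (adjusted p = 0.153), calf 24 (adjusted p = 0.0780) or calf 25 (adjusted p = 0.418), and within slide row 2 (adjusted p = 0.0641). All 11 endothelium genes were positive, with a median of 0.42 (camera adjusted p = 0.0388; adjusted p = 0.753 with an estimated correlation), led by TIE1 (0.99 ± 0.80). The list's median was 1.56 in calf 23 and -0.30, 0.06 and 0.45 in calves 21, 24 and 25. It was 0.087 without calf 23, 0.71 without calf 21 and 0.15 within slide row 1. With the preset correlation the list was called in 10 of 15 alternatives, and the call was lost without calf 23 (adjusted p = 0.840) or calf 25 (adjusted p = 0.206), and with slide row as a block (adjusted p = 0.110). The 8 B and plasma cell genes had a median of -0.27 (camera adjusted p = 0.0348; adjusted p = 0.599 with an estimated correlation) and were called in 6 of 15 alternatives that used the preset correlation. Over these 15 the list's median ran from -0.42 to 0.057. The call was lost without calf 21 (adjusted p = 0.156), calf 23 (adjusted p = 0.0962) or calf 25 (adjusted p = 0.0638), within slide row 1 (adjusted p = 0.562), and with normexp, quantile or cyclic loess processing, with no filter on dim probes (adjusted p = 0.0889) and with probes above background on all 8 arrays (adjusted p = 0.0720).

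**Figure D3:**
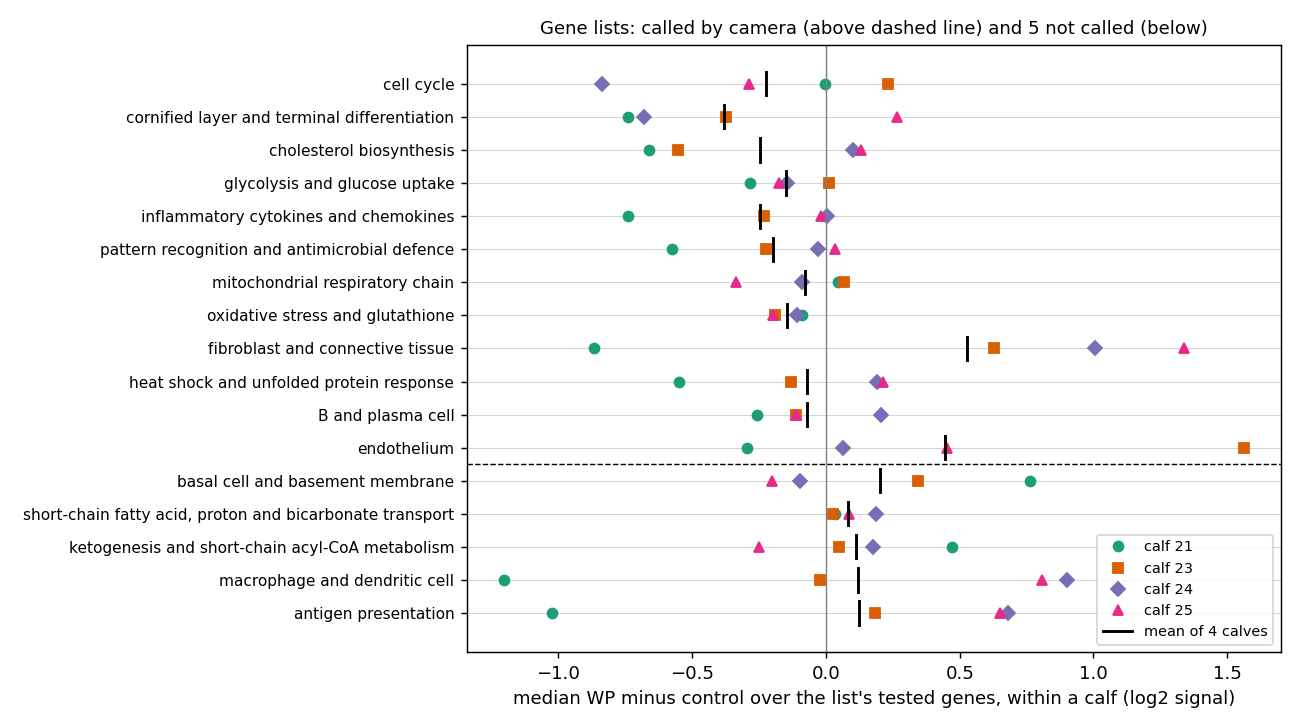
Median within-calf difference in log2 signal, WP minus control (x axis), over the tested genes of each list; points are calves, the black bar is their mean, and the dashed line parts the 12 lists called by camera from 5 that were not. The cornified layer list lies below 0 in 3 of 4 calves, and the fibroblast list runs from -0.87 in calf 21 to 1.34 in calf 25.

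Absorption and ketone body lists were not called with all 4 calves. SLC16A1, a monocarboxylate transporter of the rumen epithelium, gave 0.30 ± 0.35 (SD, n = 4), which is 0.21 above the median of all probes. Without calf 21 it was 0.15. The medians were 0.10 for short-chain fatty acid, proton and bicarbonate transport (camera adjusted p = 0.785), 0.09 for ketogenesis (adjusted p = 0.798) and 0.03 for fatty acid oxidation (adjusted p = 0.374), which was called lower without calf 21 (median -0.084, adjusted p = 0.0124) and within slide row 2 (adjusted p = 0.0436). With an estimated correlation these were lost (adjusted p = 0.607 and 0.724). The tight junction list had a median of 0.03 and a mean of -0.14 (adjusted p = 0.192), with CLDN4 at -0.54 ± 0.55 and CLDN1 at -0.38 ± 0.88. The tight junction list was called lower without calf 25 (median -0.022, adjusted p = 0.0152) and within slide row 2 (adjusted p = 0.0303), calls lost with an estimated correlation (adjusted p = 0.650 and 0.712). Without calf 23, CLDN4 was -0.35 and CLDN1 -0.070. KRT5, a basal keratin, gave -0.02 ± 0.67, SLC9A3, a sodium and proton exchanger above background on 3 of 4 WP arrays, 0.41 ± 1.36, and IGFBP5 0.32 ± 0.97. SLC9A3 and IGFBP5 turned to -0.26 and -0.076 without calf 24, and KRT5 to 0.16. Growth factors and receptors had a median of 0.32 (adjusted p = 0.374) and were called higher within slide row 2 (adjusted p = 0.0107; adjusted p = 0.712 with an estimated correlation). The free fatty acid receptor list had a median of 0.41 (adjusted p = 0.276), fatty acid and triglyceride synthesis 0.15 (adjusted p = 0.356) and xenobiotic metabolism 0.09 (adjusted p = 0.888). Sodium, potassium, chloride and mineral transport had a median of 0.01 (adjusted p = 0.280), amino acid and peptide transport -0.03 (adjusted p = 0.842), desmosome -0.05 (adjusted p = 0.239) and interferon response 0.02 (adjusted p = 0.276). Antigen presentation gave 0.12 (adjusted p = 0.978), macrophage and dendritic cell 0.12 (adjusted p = 0.978), T and NK cell -0.04 (adjusted p = 0.693) and smooth muscle 0.33 (adjusted p = 0.0577). All 8 tested smooth muscle genes were positive, with list medians of 0.17, 0.40, 0.50 and 0.044 in calves 21, 23, 24 and 25. The smooth muscle list had the smallest unadjusted directional p in fry, 0.0664 (adjusted p = 0.687). In camera with an estimated correlation its adjusted p was 0.599. Without calf 21 antigen presentation was called higher (median 0.50, adjusted p = 0.000445), as were macrophage and dendritic cell (median 0.40, adjusted p = 0.00724) and smooth muscle (median 0.34, adjusted p = 0.0350). With an estimated correlation each of these 3 had an adjusted p of 0.607. The erythrocyte and the neutrophil and mast cell lists had 3 tested genes each and no test. For 9 of the 17 lists tested and not called, camera's direction, which is relative to all other genes, opposed the sign of the median or mean.

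In all, camera called 12 of 29 lists, 10 lower and 2 higher. With an estimated correlation 0 were called, and 1 list, oxidative stress and glutathione, lay under an unadjusted 0.05. The estimate was 0.52 for cell cycle, 0.26 for cornified layer, 0.35 for cholesterol, 0.55 for mitochondrial and 0.58 for endothelium, against the preset of 0.01. It was lowest for oxidative stress among the called lists, at -0.0069. A preset below the correlation among a list's members gives p-values that are too small. In fry 0 of 29 lists passed after adjustment. With slide row as a second block 10 lists were lower and 1 higher; within row 1, 8 were lower and 1 higher, and within row 2, 12 were lower and 2 higher. In each of these 3 settings 0 were called with an estimated correlation.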

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

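The comparison with random lists and the splits of the arrays were set before their results were seen. Leaving out calf 24, quantile scaling and slide row as a second block were set out before the data were read, but their use as tests of an explanation here, like the tests on the basal cell list and on signals per slide row, was chosen after the results were seen. An array was singled out where it stood far from the other 3 of its diet. Of 224 groups of 4 examined, 13 held such an array, and chance gives 11.2. The WP array of calf 24 had 73 outlier-flagged spots (2 to 6 on the other WP arrays) and a mean correlation of 0.964 with the other arrays (0.978 to 0.980). A signal also appeared in control probes outside the comparison: E1A probes read 40.7 on that array.

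On the log2 scale relative to an array's 75th percentile, AHSG stood at -0.97 on the control array of calf 23 (others -2.44 to -2.20) and SLC9A3 at -4.21 on the control array of calf 24 (-3.90 to -3.88). On WP arrays, MN1 stood at -2.73 in calf 21 (-3.99 to -3.85), KRT10 at 0.65 (-0.90 to -0.66) and ASNS at -0.45 (-0.78 to -0.73) in calf 25, and GPX4 at 1.41 in calf 24 (1.12 to 1.15). Among mean levels of lists on WP arrays, cell cycle stood at -0.33 in calf 21 (-0.92 to -0.87), sodium and mineral transport at -0.53 in calf 21 (-0.68 to -0.65), B and plasma cell at -1.87 in calf 23 (-1.75 to -1.73), interferon response at -2.42 in calf 23 (-1.97 to -1.92) and basal cell and basement membrane at 0.83 in calf 25 (1.14 to 1.16).

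The first pattern is the lower shift of 10 gene lists on the WP diet. The arrays of calf 24 are not needed for most of these calls: 9 of the lists were shifted lower by camera with the preset correlation without that calf. The cell cycle call was lost (adjusted p = 0.0783). With an estimated correlation 0 lists were called without calf 24. How much its raised control-spot signal adds cannot be told from a count of calls, because other splits of the arrays reached similar counts. For a trend of the difference with brightness, all 10 medians lay below the lowest 2.5% of 10000 random lists matched on mean expression. The middle values of those random lists ran from 0.0033 to 0.11. That bound cannot decide the question, because the random genes were drawn independently while list members are correlated. The 10 lists had also been picked as lower in these same data. With quantile scaling 6 of them were called lower. A lower share of epithelium in the WP biopsies stays open. The basal cell list had a median of 0.25, but 0.077 without calf 21, and in 2 of the 3 calves with a negative cornified median it was positive. Lists of other cell types lay on both sides of 0. Medians were 0.61 for fibroblast, 0.42 for endothelium, 0.33 for smooth muscle and 0.12 for macrophage and dendritic cell. They were -0.27 for B and plasma cell and -0.04 for T and NK cell. Of these lists smooth muscle alone had a positive median in every calf. Of the 8 splits of the arrays that part all 4 calf pairs, 2 called 12 lists, the real one and the split by slide row. At least 10 lists were called in 4 of the 8. The split that exchanges the diets of calf 25 alone called 11, of which 10 were lower. With 8 splits the share cannot go under 0.125. An effect of the diet, which the design names, stays among the open explanations, untested.

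The second pattern is the excess of higher over lower values among dim probes on the WP diet. The raised signal of calf 24 is a candidate explanation for part of it: the median difference of dim probes was 0.22 with all calves and 0.10 without calf 24, and 264 probes were then higher at an unadjusted p under 0.05, against 256 by chance in 1 direction. Among dim probes 209 were still higher and 99 lower without calf 24, against 453 and 63 with all calves. A scaling that leaves a trend with brightness may add to it. Quantile scaling gave 192 higher against 336 lower among all 10236 probes, and dim probes were not counted apart. This cannot decide the question, because quantile scaling gives all arrays the same distribution whatever the source of the excess.

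The third pattern is a difference between the slide rows at least as large as that between the diets. With calf as a block, 1020 probes differed between rows at an unadjusted p under 0.05, against 715 between diets. Of the 8 splits that part all pairs, 3 had at least 715 probes, the real one included. With row as a second block 1017 probes differed between diets. Hybridisation position cannot be told apart from the feeding period, because the row may coincide with the period of each calf and the period is not given in the sources used here. Mean 75th percentile signals were 223 in row 1 and 282 in row 2 (exact permutation p = 0.0571, two-sided). By the same exact test negative control signal gave p = 0.457, local background p = 0.114 and probes above background p = 0.229, and the ranges of the rows met or overlapped in each of the 4 measures. That test regroups all 8 arrays and ignores the pairing by calf. Within every calf the 75th percentile signal and the local background were higher on row 2. Negative control signal and probes above background did not go 1 way in every calf. With the pairing kept, an exact test over 4 calves cannot go under 0.125. For genes past the adjusted threshold, the real split and the highest other both gave 0, so 8 of 8 splits had as many.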

How the results depend on the processing

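Cyclic loess scaling, bright probes alone and the comparisons within slide rows were chosen after seeing the data. No setting run called a gene at an adjusted p of 0.05, and 0 passed 0.10 with the main processing; 353 probes had an unadjusted p under 0.05 and at least 1.5-fold, a looser criterion by construction. In the paired comparison, leaving out the calf block gave 0 genes, 599 probes higher and 186 lower at an unadjusted p under 0.05 and 12 lists, and changed no call of a list. With all calves, 536 probes were higher and 179 lower. Lower probes numbered 349 with slide row as a second block and 101 with no filter on dim probes. Normexp gave 1134 higher and 293 lower, quantile scaling 192 and 336, cyclic loess 263 and 411, bright probes alone 191 and 215, and slide row 2 alone 355 and 109. Leaving out each calf gave 264 to 714 higher and 69 to 221 lower. The cause of these moves was not tested, except that fewer probes or arrays enter the restricted settings.

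Of the 12 lists, 0 were called with an estimated correlation (0 higher, 0 lower). Lists shifted lower numbered 6 with quantile scaling and 8 to 9 without 1 calf. Lists shifted higher numbered 1 with slide row as a block, 0 with no dim filter, 1 with bright probes alone, 1 within slide row 1, and 0 to 5 without 1 calf. The cause was not tested. Over 190 list values under alternatives, 159 stayed called, 31 did not and 0 turned camera's direction, which is relative to all other genes. Medians did change sign, to 0.046 for pattern recognition and 0.057 for B and plasma cell with no dim filter, and to 0.049 for heat shock and 0.0090 for the cytokine list without calf 21. Cornified layer, cholesterol biosynthesis, glycolysis and pattern recognition were called in 16 of 16 alternatives that used the preset correlation, with medians from -0.72 to -0.16, -0.45 to -0.025, -0.24 to -0.12 and -0.38 to 0.046.

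Of 80 genes that the naming rule takes, 64 kept their sign in every alternative, and over 1388 gene values 26 turned; the smallest adjusted p was 0.309. With normexp, BTBD17 was 0.050, IL1B 0.13 and PFKFB4 0.13. With quantile scaling, BCL2L10 was -0.11, GNAQ -0.078, TLR4 -0.34 and UQCRB -0.53; with cyclic loess, TLR4 was -0.27 and UQCRB -0.40. Within slide row 1, BCL2L10 was -0.87, ASMT -0.13, KRT5 0.15, SLC9A3 -0.12, KRT10 -0.38, PRDX6 0.22 and TALDO1 0.046; within row 2, TLR4 was -0.041, SDHA 0.42 and HSPA1A -0.078. Leaving out each calf in turn gave KRT5 values from -0.23 to 0.18, TLR4 from -0.24 to 0.31, SLC9A3 from -0.26 to 0.76, IGFBP5 from -0.076 to 0.68 and IL1B from -0.65 to 0.43. The cause was not tested.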

Other observations

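The genes in this part were chosen after their values were seen. The arrays fall into slide row 1 (WP of calves 21 and 23, control of calves 24 and 25) and row 2 (the converse), and 19 probes differed between the diets by at least 1 log2 in each calf, with opposite signs in calves 21 and 23 and calves 24 and 25, the rule by which they were picked. Of these, 14 were higher and 5 lower on row 2. CD48, a leukocyte surface protein, had a mean level of -2.21 on row 1 and 0.88 on row 2 (log2 relative to the 75th percentile, adjusted p = 0.0965 in limma), CYP2C90 was higher by 1.99 and PRODH by 1.31. The T cell receptor chain CD3D was well above background on 1 row 1 array and 3 row 2 arrays, and complement C3 and the chemokine CCL28 on 1 and 4, so no size is given for them. SELENOW and IGFBP6 went the other way, by -2.08 and -2.04, as did PDLIM4 by -1.51. None of these passed an adjusted p of 0.05 between rows. Of 10194 probes with a value on all arrays, 21.1% had such opposite signs of any size, against 12.5% by chance. Of all 10236 probes tested 17.3% had the same sign in 4 of 4 calves, where chance also gives 12.5%.

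By camera on the split by row, the macrophage and dendritic cell list (adjusted p = 0.000222), the T and NK cell list (adjusted p = 0.0165), antigen presentation (adjusted p = 0.00664) and cholesterol biosynthesis (adjusted p = 0.000146) were lower on row 1, as were tight junction (adjusted p = 0.0117), heat shock (adjusted p = 0.00849), the cytokine list (adjusted p = 0.0406) and fibroblast (adjusted p = 0.0180). Cell cycle (adjusted p = 5.57e-07), basal cell and basement membrane (adjusted p = 0.000139), fatty acid oxidation (adjusted p = 0.000139) and the mitochondrial respiratory chain (adjusted p = 0.00219) were higher there. With an estimated correlation 0 lists were called on that split (smallest adjusted p = 0.545). Of these 12 lists, cholesterol biosynthesis, cell cycle, heat shock, cytokine, fibroblast and mitochondrial were also called between the diets. Within calves, the macrophage and dendritic cell median for WP minus control was -1.20 and -0.02 in calves 21 and 23 and 0.90 and 0.81 in calves 24 and 25.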
